A study of Rattus norvegicus with 6 samples.

How the data were processed

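RNA sequencing of rat pancreas was analysed from the authors' deposited table of gene-level TPM, with 1 column per library and 34001 genes. Per the labels' protocols, RNA was extracted with a column kit and libraries were built from total RNA with a SMARTer mRNA kit. The aligner and the program that made the TPM values are not given in the sources used here. The submitters' processing notes name the mouse builds GRCm38 and mm10, while 32883 genes carry rat Ensembl identifiers and 1118 carry MSTRG identifiers with no gene name; which annotation was used was not settled. Gene names were taken from the table, and no coordinates were used. Each library column sums to 1000000 TPM, so the deposited values hold no depth, and no counting error could be given. The authors' 3 group-mean TPM columns equal the means of the 2 library columns and were not tested. Library columns named for the TP group carry a number that no label explains; they were assigned by name and replicate number. Gene length was read but entered no test.

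Samples were grouped by their titles, with 2 rats in each of 3 groups, and 3 comparisons were made. Genes with a mean TPM of at least 1 over the 6 libraries were kept, 11477 in all; 14485 genes were at 0 in all libraries. Values were transformed to log2(TPM + 0.5). One linear model over the 6 libraries was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a variance trend, leaving 3 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. The prior degrees of freedom were infinite, so that genes of similar abundance shared 1 variance; the median standard error was 1.43. TPM are not counts, so no count model was used. The series describes separate rats. P-values rest on 1 variance pooled over the 3 groups, also where the TP group is not compared. The 2 TP libraries, the least alike within a group, add most to it. Leaving out either TP library takes their difference out of the variance, which by itself raises the number of genes called.

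Gene lists, 31 in all, for cell types and pathways of injured pancreas were fixed before the data were examined, as were the main design, the alternatives and the rule for named genes. Lists were compared with all other genes by camera of limma, with a preset correlation of 0.01, and again with an estimated correlation. Named genes were, per comparison, up to 10 in each direction with the largest change among genes past the threshold whose libraries did not overlap and which had a proper symbol, filled up to 5 with genes of smallest p that did not pass. To these were added per list the 2 members past the threshold with the largest change, or all where 5 or fewer passed, and the 2 with the highest mean TPM, and the 10 genes of highest mean TPM. Ca3, LOC286960, AABR07018115.1, AABR07072539.7, MSTRG.10538, AC128792.1, AC119336.1 and AC111734.1 passed the threshold but fall outside that rule, and were chosen after their values were seen, as were Sncg and Scd. Not all genes that the rule names are given in the text, and 1 was left out of all reported values.

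The analysis was tested on simulated data for 11477 genes drawn independently. The spread of each gene was pooled over the groups and made equal in all of them, with no library-wide shifts, unlike the real libraries. For the TP group against control, 0% of genes changed by 2 log2 units were recovered, 14% at 4, 64% at 6 and 94% at 8. For TP+hucMSC-Exs against TP the shares were 2%, 18%, 80% and 96%, and against control 0%, 30%, 66% and 96%. False calls among unchanged genes numbered 6, 3 and 1 in the 3 comparisons, beside the calls of 200 changed genes, which loosen the adjustment. Simulations with no changed gene, 100 of each kind, were added after the results were seen. They drew genes independently and held no shift of a whole group, while the data hold correlated genes and such shifts. They therefore set no chance level for the observed counts. With equal, independent spread in all groups they called a mean of 0.05, 0.08 and 0.04 genes. With each group's own spread they called 0 genes, but the prior degrees of freedom were 2.94, unlike those of the data. With library-wide shifts kept as well, the prior degrees of freedom were infinite as in the data, and they called a mean of 1.93, 1.63 and 0 genes, at most 5, 6 and 0. Changes of up to 4 log2 units were therefore mostly not called under equal spread. Recovery with the unequal spread and library-wide shifts of the real libraries was not simulated.

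Alternatives were another pseudocount (0.1 or 1), no filter or a mean TPM of at least 5, and no variance trend. Others were TPM rescaled without the digestive enzymes of the list, median-of-ratios scaling and quantile normalization. That rescaling kept the abundant exocrine genes LOC103689940 and LOC103690354, which the list does not name. The rest were only the groups compared, the replicate number as a block, an additional log2 fold change of at least 1, and leaving out each library. Added after the data were seen were median-of-ratios scaling with TP replicate 2 left out, library weights, leaving out libraries for the enzyme share, and 2 further references for the covariance of injury and exosome changes. The first reference kept library-wide shifts in the spread; since a shift common to all genes adds nothing to a covariance across genes, one with library means removed and the spread of the TP libraries alone were added after its result was seen, and all 3 are printed. Figures were drawn with matplotlib 3.10.9.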

Results

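RNA was sequenced from the pancreas of 6 Sprague-Dawley rats, an outbred laboratory strain, in 3 groups of 2 rats. Control rats had the abdomen opened and the pancreas handled with swabs, and received 1 ml of saline into the tail vein. In the TP group (traumatic pancreatitis) the gland was crushed with an impactor set to 3 cm2 and 10 kg, followed by saline. In the TP+hucMSC-Exs group the same injury was combined with exosomes, small membrane vesicles released by cells, from human umbilical cord mesenchymal stem cells at 10 μg per 100 g of body weight. Tissue was taken 24 h after injury. Values were TPM, transcript abundances scaled by gene length to the same total in every library, which keep no sequencing depth, so depth was unknown. Log2 fold changes are on the scale of log2(TPM + 0.5), which understates the change of low genes, and are given with their standard error (SE), with n = 2 libraries per group.

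Transcripts of acinar digestive enzymes, the secreted proteins of the exocrine pancreas, dominated the tissue. The 20 measured genes of this list and 3 below the expression filter together took 76.7% and 73.5% of all TPM in the control libraries, a mean of 75.1% ± 2.26 (SD, n = 2). In the TP group the share was 69.0% in replicate 1 and 18.7% in replicate 2, a mean of 43.9% ± 35.6 (SD, n = 2). In the TP+hucMSC-Exs group it was 59.8% and 54.8%, a mean of 57.3% ± 3.56 (SD, n = 2). The list was matched by gene symbol, so it lacks the abundant LOC103689940, described as pancreatic alpha-amylase-like, and LOC103690354, a pancreatic ribonuclease. They stood at 58866 and 26277 TPM in control replicate 1 and at 18271 and 6726 TPM in TP replicate 2. The shares therefore leave out part of the exocrine transcripts. The single most abundant transcripts were Prss1, a trypsinogen, with a mean of 151771 TPM over the 6 libraries, and Ctrb1, chymotrypsinogen B, with 149543 TPM. With 2 libraries against 2, the smallest two-sided p-value of an exact permutation test is 0.333, so that test could not pass a threshold of 0.05 for these shares.

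**Figure D1:**
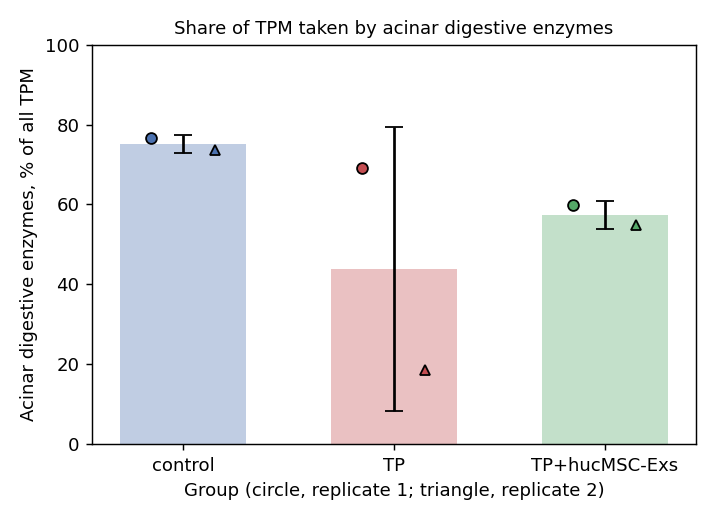
Share of all TPM taken by the acinar digestive enzymes of the list, in percent, by group. Bars are means of 2 libraries, error bars are 1 SD, and points are single libraries. The TP libraries lie at 69.0% and 18.7%, the control libraries at 76.7% and 73.5%, and the TP+hucMSC-Exs libraries at 59.8% and 54.8%.

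The TP libraries differed from each other more than the libraries of either other group did. The Pearson correlation of log2 values over 11477 genes, which are not independent replicates, was 0.712 between the TP libraries, 0.939 between the controls and 0.968 between the TP+hucMSC-Exs libraries. TP replicate 1 correlated at 0.954 with control replicate 1 and at 0.930 with control replicate 2. Genes at 1 TPM or more numbered 5533 and 7863 in the controls, 6498 and 13629 in the TP libraries, and 9924 and 10537 in the TP+hucMSC-Exs libraries. Relative to the control mean, the median gene lay at 0.00 (log2) in TP replicate 1, at 3.00 in TP replicate 2, and at 0.97 and 1.22 in the TP+hucMSC-Exs libraries. The median log2 change of all genes was 1.495 for TP against control, -0.375 for TP+hucMSC-Exs against TP and 1.09 for TP+hucMSC-Exs against control, so gene lists are described relative to the median gene. TP replicate 2 also held 741 TPM of Adipoq, a hormone of fat cells, against at most 1.42 TPM in the other libraries, and 4.30% of its TPM came from mitochondrially encoded genes against 0.549% to 0.853% elsewhere.

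The comparison of the TP group with the control group asked what the crush injury changed. Reg3b (ENSRNOG00000006151), a secreted C-type lectin known from pancreatitis, rose from 200.4 and 247 TPM in the controls to 15906 and 1902 TPM in the TP libraries, a log2 fold change of 4.62 ± 0.79 (SE; adjusted p = 2.62e-05). The median gene lay 3.00 (log2) above the control mean in TP replicate 2, and at 0.00 in TP replicate 1. Relative to the median gene, the rise of Reg3b therefore rested mainly on TP replicate 1. Lcn2 (ENSRNOG00000013973), the iron-scavenging protein lipocalin 2, rose from 2.88 and 2.78 TPM to 216 and 560.0 TPM, a log2 fold change of 6.71 ± 1.27 (SE; adjusted p = 0.000528). Timp1 (ENSRNOG00000010208), an inhibitor of matrix metalloproteinases, rose by 5.79 ± 1.37 (SE; adjusted p = 0.0472), but its TP values were 13.3 and 1089 TPM. Of 11477 genes tested with limma, 6 were higher and 0 lower at an adjusted p below 0.05, and 466 had an unadjusted p below 0.05. In 100 simulations with no changed gene, a mean of 1.93 and at most 5 genes were called, against the 6 observed. They kept each group's spread and the library shifts within groups, but drew genes independently and held no shift of a whole group. They therefore set no chance level for these 6 calls. The remaining 3 were unnamed genes. AABR07072539.7 stood at 477 and 0 TPM in the controls against 721 and 2899.9 TPM, and AABR07018115.1 and MSTRG.10538 were listed at 0 in both controls. Among genes that did not pass, the chemokine Ccl2 stood at 2.89 and 248 TPM against 0 and 0.17 TPM in controls (adjusted p = 0.108), and the haem-degrading enzyme Hmox1 at 5.67 and 346 TPM against 0.08 and 1.59 TPM (adjusted p = 0.157). The lowest adjusted p among lower genes was that of the trypsinogen Prss3, with 7186 and 2254 TPM against 27099 and 25354 TPM (log2 fold change -2.70 ± 0.66, adjusted p = 0.0671); reads of trypsinogen genes can be split between near-identical copies. Without TP replicate 2 the count was 30 genes, without TP replicate 1 it was 11064, and without control replicate 1 it was 1. With limma it was 0 without control replicate 2 and without either TP+hucMSC-Exs library, where 72, 83 and 85 genes had an unadjusted p below 0.05. It was also 0 without the filter, with median-of-ratios scaling and with quantile normalization (160, 669 and 642 unadjusted), and 2, both among the 6, with TPM rescaled without the digestive enzymes.

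Against control, 16 of 31 gene lists passed the camera test of limma with its preset correlation, 10 up and 6 down relative to other genes, and 0 of them with an estimated correlation. Acinar digestive enzymes had a median log2 change of -2.48 relative to the median gene (camera adjusted p = 1.34e-89; adjusted p = 0.375 with an estimated correlation). Over all genes 0 of 20 members passed with limma, and 2 of 20 were lower adjusted over the list alone. The median of this list relative to the library's median gene was -0.11 in TP replicate 1 and -4.91 in TP replicate 2. Among the 13 measured acute pancreatic stress proteins, a list of proteins known to be induced in injured pancreas, 2 (Reg3b and Lcn2) rose, and 7 did adjusted over the list alone (camera adjusted p = 2.59e-06; adjusted p = 0.375 with an estimated correlation). This call was lost without the filter, with TPM rescaled without the digestive enzymes (adjusted p = 0.308), with median-of-ratios scaling (adjusted p = 0.282) and with quantile normalization, and turned down without TP replicate 1 (adjusted p = 1.9e-07). Inflammatory cytokines and chemokines lay 1.23 above the median gene, with 0 of 19 past the threshold and 3 adjusted over the list alone (camera adjusted p = 2.92e-08; adjusted p = 0.676 with an estimated correlation). Monocyte and macrophage genes lay 1.47 above it (camera adjusted p = 1.4e-11; adjusted p = 0.669 with an estimated correlation), and fibroblast and extracellular matrix genes 1.61 above it, with 1 of 20, Timp1, past the threshold (camera adjusted p = 3.49e-21; adjusted p = 0.502 with an estimated correlation). Adipocyte genes lay 1.75 above it, with 0 of 13 past the threshold (camera adjusted p = 5.39e-10; adjusted p = 0.669 with an estimated correlation). Without TP replicate 1 the cytokine and macrophage calls were lost (adjusted p = 0.124 and 0.201), and without TP replicate 2 the macrophage and adipocyte calls were (adjusted p = 0.0575 for both). The adipocyte call was also lost without the filter and with TPM rescaled without the digestive enzymes (adjusted p = 0.054), and turned down with median-of-ratios scaling and TP replicate 2 left out (adjusted p = 0.0305), an alternative chosen after seeing the data. These 4 lists stood at 0.16, 0.16, 0.39 and -0.49 in TP replicate 1, and at 2.20, 2.66, 3.06 and 3.86 in TP replicate 2. Examples are the macrophage gene Lyz2 at 24.4 and 3707 TPM, the collagen Col3a1 at 41.1 and 2233 TPM, and the fat-cell gene Fabp4 at 16.5 and 2399 TPM in the TP libraries.

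**Figure D2:**
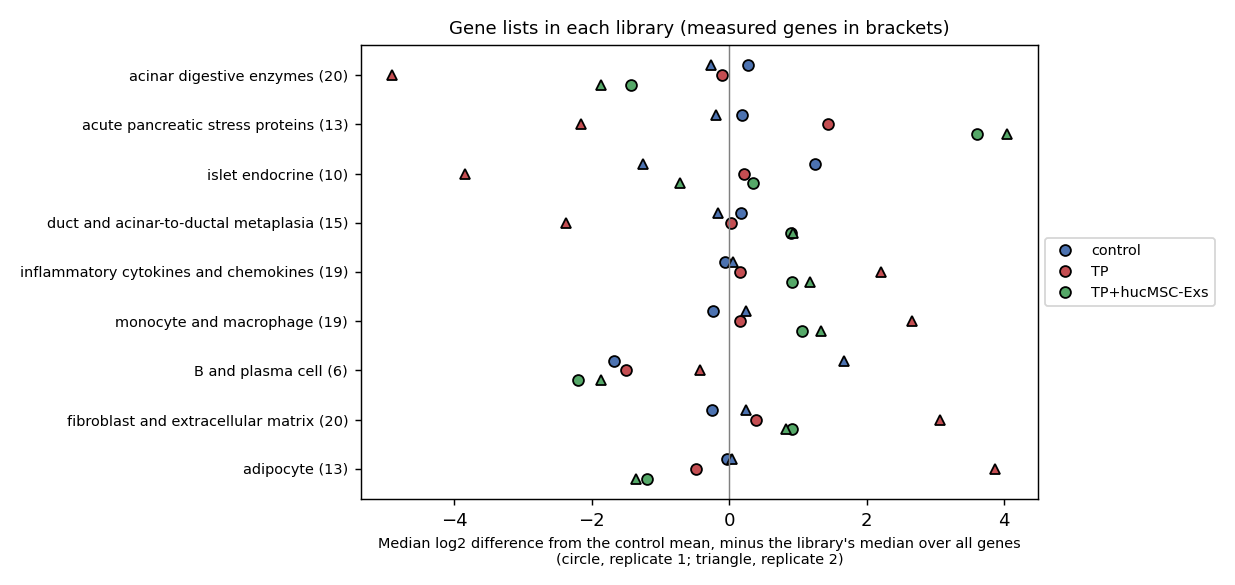
Median of 9 gene lists in each library, as the log2 difference from the control mean minus the library's median over all genes; each point is 1 library. TP replicate 2 lies at -4.91 for acinar digestive enzymes and at 3.86 for adipocyte genes, while the TP+hucMSC-Exs libraries lie highest for acute pancreatic stress proteins, at 3.60 and 4.04.

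The comparison of the TP+hucMSC-Exs group with the TP group asked what the exosomes changed in injured tissue. Try5 (ENSRNOG00000045612), a trypsin-family gene, stood at 3547 and 3040.1 TPM against 31.5 and 8.92 TPM, a log2 fold change of 7.56 ± 1.19 (SE; adjusted p = 2.69e-06). Reg3g (ENSRNOG00000006579), another secreted lectin of the Reg3 family, stood at 756 and 1781 TPM against 75.3 and 1.40 TPM (6.60 ± 1.39, adjusted p = 0.00593). Nupr1 (ENSRNOG00000019206), a stress-induced nuclear protein, stood at 4405 and 5874 TPM against 114 and 122 TPM (5.43 ± 1.04, adjusted p = 0.00105). Clu (ENSRNOG00000016460), the chaperone clusterin, stood at 9861 and 14148 TPM against 289.9 and 509 TPM (4.94 ± 1.02, adjusted p = 0.00491). Hpx (ENSRNOG00000018257), the haem-binding protein hemopexin, stood at 50.9 and 157 TPM against 0.77 and 0.72 TPM (6.17 ± 1.43, adjusted p = 0.0214). LOC286960, which the annotation of the table describes as a preprotrypsinogen, stood at 4894 and 7559 TPM against 784 and 186 TPM (3.99 ± 0.91, adjusted p = 0.0179). Of 11477 genes, 6 were higher and 2 lower with limma, and 152 had an unadjusted p below 0.05. The same simulations, with the same limits, called a mean of 1.63 and at most 6 genes, against the 8 observed. The lower genes were Ca3, carbonic anhydrase 3 of muscle and fat, whose TP libraries did not separate from the treated ones (0 and 3475 TPM against 0.03 and 0.05 TPM), and AABR07018115.1, at 41.5 and 48.5 TPM in the TP libraries and listed at 0 in the other 4. Try5 and LOC286960 belong to a family of similar genes, so their split of reads is uncertain. Without TP+hucMSC-Exs replicate 1 or 2 limma called 0 genes (34 and 33 unadjusted); without either control library the count was 1, without TP replicate 1 it was 9893 and without TP replicate 2 it was 3604. None of the 8 was called without the filter or with quantile normalization, where limma called 0 genes (315 and 983 unadjusted), or among the 2 genes called with median-of-ratios scaling; with TPM rescaled without the digestive enzymes 2 were called, both among the 8.

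**Figure D3:**
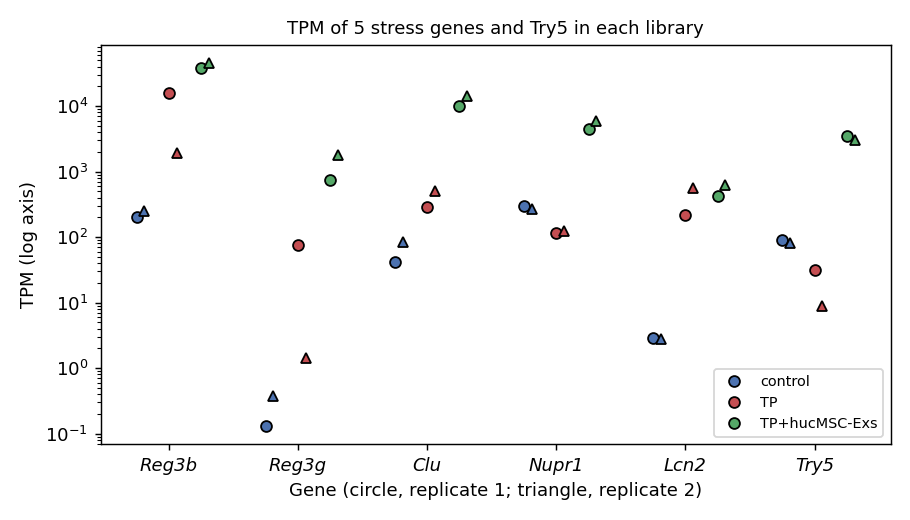
TPM on a log axis of 5 stress genes and Try5; each point is 1 library of the control, TP or TP+hucMSC-Exs group. Both TP+hucMSC-Exs libraries lie above the other 4 for Reg3b, Reg3g, Clu, Nupr1 and Try5, while for Lcn2 the TP replicate 2 value of 560.0 TPM lies between their 431 and 632 TPM.

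Of the 31 lists, 17 passed camera in this comparison, 8 up and 9 down, and 2 with an estimated correlation. Those 2, the stress proteins and the duct genes, had estimated correlations of 0.044 and 0.031, against 0.327 to 0.995 for the other lists. The estimate rests on 3 residual degrees of freedom, to which the difference between the TP libraries adds most. Passing therefore depended on a low estimated correlation as well as on the change. Acute pancreatic stress proteins lay 2.96 above the median gene; 3 of 13 rose (Reg3g, Clu and Nupr1) and 6 did adjusted over the list alone (camera adjusted p = 1.16e-55; adjusted p = 0.0261 with an estimated correlation). Genes of duct cells and acinar-to-ductal metaplasia lay 1.73 above it; 0 of 15 passed over all genes and 4 did adjusted over the list alone (camera adjusted p = 8e-22; adjusted p = 0.0479 with an estimated correlation). Of this list, the keratin Krt8 stood at 412 and 519 TPM against 49.0 and 35.6 TPM in the TP group and 32.2 and 34.9 TPM in control. Anxa2, another abundant member, stood at 143 and 200 TPM, between the TP values of 17.0 and 1160 TPM. As a share of TPM the whole list took 0.0973% and 0.124% in the treated libraries, against 0.0158% and 0.128% in the TP libraries. The rise over TP replicate 2 was therefore relative to the median gene only. Acinar digestive enzymes lay 0.76 above the median gene (camera adjusted p = 3.21e-19; adjusted p = 0.638 with an estimated correlation), with Try5 the 1 member past the threshold, but 69.0% of TPM in TP replicate 1 was above both treated libraries and the list turned down without TP replicate 2 (adjusted p = 1.85e-43). Adipocyte genes had a median of -2.65 relative to it (camera adjusted p = 1.87e-30; adjusted p = 0.421 with an estimated correlation), fibroblast genes of -1.04 (camera adjusted p = 1.62e-05; adjusted p = 0.908 with an estimated correlation), and both calls were lost without TP replicate 2 (adjusted p = 0.177 and 0.334). Islet endocrine genes lay 1.63 above it (camera adjusted p = 4.28e-08; adjusted p = 0.638 with an estimated correlation), a call that turned down without TP replicate 2 (adjusted p = 0.00636). Both the enzyme and the islet calls were lost in camera with median-of-ratios scaling (adjusted p = 0.168 and 0.135) and with quantile normalization. The fibroblast call was also lost without the filter. Cytokines and chemokines did not pass (camera adjusted p = 0.955) but lay up without TP replicate 2 (adjusted p = 0.0165). Monocyte and macrophage genes (camera adjusted p = 0.579) and NF-kappaB genes (camera adjusted p = 0.394) did not pass either, and without TP replicate 2 both pointed up without passing (adjusted p = 0.0957 and 0.0525). Mitochondrially encoded genes had a median of -1.002 relative to the median gene, with 0 of 12 past the threshold in limma (camera adjusted p = 5.34e-09; adjusted p = 0.638 with an estimated correlation). Ccl2 stood at 24.1 and 48.9 TPM, between the TP values of 2.89 and 248 TPM.

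The comparison of the TP+hucMSC-Exs group with the control group asked how treated injured tissue differed from uninjured tissue. Reg3g had a log2 fold change of 10.61 ± 1.39 (SE; adjusted p = 1.28e-10), Clu of 7.64 ± 1.02 (adjusted p = 2.73e-10), Reg3b of 7.56 ± 0.79 (adjusted p = 1.15e-17) and Lcn2 of 7.29 ± 1.27 (adjusted p = 1.95e-05). Reg3b reached 38509 and 45798 TPM. In all, 24 genes were higher and 0 lower with limma, and 338 had an unadjusted p below 0.05. Of the 24, AC128792.1, AC119336.1 and AC111734.1 held identical values in every library, 14.7 and 49.02 TPM in the treated libraries and 0 in the other 4, and AABR07072539.7 had the control values of 477 and 0 TPM. The same 100 simulations with no changed gene called 0 genes in any draw. They held no shift of a whole group, while the median gene lay 1.09 higher in the data. They therefore set no chance level for the 24 calls. Hpx (7.03 ± 1.43, adjusted p = 0.00137), Tspan1, Sectm1b, Tnfrsf12a and Neurl3 also rose, the last 4 with adjusted p between 0.0137 and 0.0245. Hamp, encoding the iron hormone hepcidin, was listed at 0 in both controls and in TP replicate 1 and stood at 26.3 and 55.01 TPM (adjusted p = 0.0137). Ccl2 stood at 24.1 and 48.9 TPM (5.91 ± 1.43, adjusted p = 0.0245), and Cldn4, a tight-junction protein of duct epithelium, at 34.98 and 49.5 TPM against 0.36 and 0.35 TPM (5.62 ± 1.43, adjusted p = 0.0397). Without TPM of the digestive enzymes the counts were 5 higher and 1 lower, 5 of them among the 24, and with median-of-ratios scaling 2 and 0, 1 of them among the 24. Without the filter and with quantile normalization limma called 0 genes (368 and 1100 unadjusted). Without TP+hucMSC-Exs replicate 2 the count was 1 gene, Reg3b, and without TP+hucMSC-Exs replicate 1 it was 3. Without control replicate 1 it was 4 and without control replicate 2 it was 3; without TP replicate 1 it was 6094 and without TP replicate 2 it was 6135.

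In this comparison 22 of 31 lists passed camera, 14 up and 8 down, and 1 with an estimated correlation. That 1 was the stress protein list, with its low estimated correlation of 0.044. Acute pancreatic stress proteins lay 3.86 above the median gene; 7 of 13 rose and 10 did adjusted over the list alone (camera adjusted p = 9.76e-95; adjusted p = 0.0117 with an estimated correlation). Duct and metaplasia genes lay 0.91 above it, with 1 of 15, Cldn4, past the threshold and 6 adjusted over the list alone (camera adjusted p = 1.28e-08; adjusted p = 0.194 with an estimated correlation). Cytokines and chemokines lay 1.04 above it (camera adjusted p = 6.56e-08; adjusted p = 0.734 with an estimated correlation) and monocyte and macrophage genes 0.98 above it (camera adjusted p = 6.86e-09; adjusted p = 0.734 with an estimated correlation). Digestive enzymes had a median of -1.64 relative to it (camera adjusted p = 3.7e-24, and adjusted p = 0.698 with an estimated correlation). This call was also lost with quantile normalization. Of this list Try5 rose (5.26 ± 1.19, adjusted p = 0.0134), and the lipase Pnlip stood at 10359 and 7186 TPM against 21253 and 22320.1 TPM, and did not pass (adjusted p = 0.8). Mitochondrially encoded genes had a median of -1.01 relative to the median gene, with 0 of 12 past the threshold in limma (camera adjusted p = 5.22e-05; adjusted p = 0.734 with an estimated correlation). B and plasma cell genes had a median of -2.00 relative to it, with 0 of 6 past the threshold in limma (camera adjusted p = 6.56e-08; adjusted p = 0.698 with an estimated correlation), but the control libraries themselves stood at -1.67 and 1.67, and the call was lost without control replicate 2.

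Whether exosome treatment moved genes opposite to injury was examined across genes, which are not independent replicates. The log2 changes of the injury and exosome comparisons had a Pearson correlation of -0.51. Both comparisons contain the TP libraries with opposite sign. In 1000 simulations with no effect and the same spread in all groups, the mean was -0.50, a value that equal spread fixes whatever the data. The real TP libraries were less alike than those of the other groups, so -0.50 sets no chance level for the observed correlation. The covariance was -0.335. The reference used first, simulations with library shifts kept, gave -1.04. Of 2 references added after that result was seen, simulations with library means removed gave -0.161 and the spread of the TP libraries alone gave -0.529, so the sign of the difference depended on the reference. When injury was taken from TP replicate 1 and the exosome comparison from TP replicate 2, so that no TP library was shared, the covariance was 0.068, and 0.320 with the libraries exchanged. Only 1 gene, AABR07018115.1, was past the threshold in both comparisons with opposite signs, and 0 with the same sign. Independent lists would give 0.001 such genes, a value that leaves out the TP libraries shared with opposite sign.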

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

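Of the alternatives, median-of-ratios scaling with TP replicate 2 left out and library weights were chosen after seeing the data. Counts are for TP against control, TP+hucMSC-Exs against TP, and TP+hucMSC-Exs against control, in that order, where the main analysis called 6, 8 and 24 genes. Without the filter limma called 0, 0 and 0 (160, 315 and 368 at an unadjusted p below 0.05). With TPM rescaled without the digestive enzymes it called 2, 2 and 6; with median-of-ratios scaling 0, 2 and 2 (669, 824 and 1069 unadjusted); with quantile normalization 0, 0 and 0 (642, 983 and 1100 unadjusted). With only the 2 groups compared it called 0, 1 and 6550 (81, 58 and 6964 unadjusted), and with library weights 0, 0 and 7922 (38, 42 and 8393 unadjusted), since the spread of the TP libraries then no longer entered the third comparison or counted little. With a pseudocount of 0.1 the first count was 14, and with a pseudocount of 1 the third was 12. With median-of-ratios scaling and TP replicate 2 left out the second was 68 and the third 789. The cause of the other changes was not tested. With median-of-ratios scaling the median change of all genes was 0.02, -0.02 and 0.00 in place of 1.495, -0.375 and 1.09. The calls of the second comparison split 2 higher and 0 lower with median-of-ratios scaling and without the enzymes, against 6 and 2, and those of the third 5 and 1 without the enzymes, against 24 and 0. None of the 2 genes called against TP with median-of-ratios scaling was among the 8 of the main analysis.

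The lists past the threshold numbered 16, 17 and 22. With an estimated correlation they numbered 0, 2 and 1. Without the filter the second count was 11, and with median-of-ratios scaling and TP replicate 2 left out the first was 10. The stress protein list kept its direction and its side of the threshold in all 18 alternatives in both comparisons of the TP+hucMSC-Exs group, and the duct and metaplasia list did in all 18 against TP.

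Leaving out each library in turn, with a lone sample assumed to vary like the other groups, gave 0 (without control replicate 2 or either TP+hucMSC-Exs library) to 11064 genes (without TP replicate 1) in the first comparison, 0 to 9893 in the second and 1 to 6135 in the third. Lists ranged from 10 to 18 in the first and from 10 to 18 in the second. The correlation of injury and exosome changes ranged from -0.83 to -0.33. Several named genes changed sign in the exosome comparison depending on which TP library was used. The log2 changes ranged from -12.65 to 0.11 for Ca3 (0.06 with median-of-ratios scaling and TP replicate 2 left out), -0.61 to 1.31 for Zg16, -2.83 to 3.36 for Ccl2, -3.54 to 2.00 for Ccl7, -2.64 to 4.08 for S100a8, -2.49 to 4.47 for S100a9, -3.33 to 3.96 for Gpnmb and -2.77 to 3.28 for Anxa2. They ranged from -1.65 to 1.02 for Plvap, -2.93 to 1.60 for Eng, -3.64 to 1.66 for Msln, -3.01 to 1.20 for Calr, -2.43 to 2.41 for Sod2, -1.76 to 2.77 for Nfkbia, -2.37 to 1.64 for Ninj1, -2.68 to 2.03 for Pycard and -2.41 to 2.09 for Gpx1. They ranged from -4.94 to 1.87 for Mt2A, -2.10 to 2.79 for Ctsb, -1.47 to 1.82 for Ctsl, -1.18 to 3.90 for Ifi27, -2.59 to 2.29 for Eno1, -3.00 to 2.18 for Ldha, -1.003 to 1.08 for LOC103689940, -0.61 to 1.31 for Clps, -0.60 to 1.28 for Cela2a, -0.73 to 1.06 for Cpa1 and -0.82 to 0.95 for LOC103690354. In the injury comparison Reg1a ranged from -1.08 to 1.16. Leaving out either TP library takes the difference between the TP libraries out of the only estimate of spread, which by itself raises the counts of genes called. The cause of the changes of sign was not tested beyond the library left out.

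With the replicate number as a block (a replicate block), limma called 10, 22 and 35 genes, among them all 6, 8 and 24 of the main analysis. Whether libraries of the same number are paired was not settled, since 2 numbers are too few to show it and the labels do not say; they were taken to share only a number. The correlation across genes of replicate 1 minus replicate 2 was 0.28 between control and TP, 0.08 between control and TP+hucMSC-Exs and 0.14 between TP and TP+hucMSC-Exs. Depth is unknown in TPM, so no limit from counting error could be set.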

Other observations

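The tests of the acinar share, of a mislabelled sample, of TPM composition, of TP replicate 2 alone and of shared TP libraries were chosen only after their results were seen; those of adipose, STAT3 and gastric genes were set before, except for a requirement on their counting interval added to the STAT3 and gastric tests once the gastric result was seen. Control replicate 2 held lymphoid transcripts at levels unlike the other control. The homing ligand gene Glycam1 stood at 52.7 TPM there and at 0 in control replicate 1, and the chemokine gene Ccl21 at 125 and 1.66 TPM. Relative to each library's median gene, T and NK cell genes lay at -1.23 and 1.23 in control replicates 1 and 2, and MHC class II genes at -1.45 and 1.45. Islet genes went the other way, at 1.25 and -1.25, with Ins2 at 1078 and 167 TPM. Mitochondrially encoded genes lay at -0.87 and -1.24 in the TP+hucMSC-Exs libraries. Their lower calls in both comparisons of that group were lost only with an estimated correlation among 18 alternatives, but are relative to other genes. As a share of TPM these genes took 0.783% and 0.728% there, between the controls' 0.549% and 0.853%. Their median log2 change against control was 0.081. After median-of-ratios scaling, 147 genes were at least 1 log2 unit higher in both TP+hucMSC-Exs libraries than in all 4 others, more than for any other of the 15 pairs of libraries. The next, control replicate 2 with TP replicate 2, had 68. Such a count also depends on how alike the 2 libraries of a pair are. The TP+hucMSC-Exs pair was the most alike of the 15, with an SD of the log2 difference of 0.448, against 1.405 for the TP pair.

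TP replicate 2 stood apart from TP replicate 1. A lower share of acinar RNA alone would raise other cell types together, but the islet list minus the fibroblast list was -7.03 log2 units in the difference between the TP libraries (-1.37 and 5.66). A mislabelled control in the place of TP replicate 1 is argued against by 7 of 13 stress proteins lying at least 1 log2 unit above both controls there after median-of-ratios scaling. Adipose tissue in the sample of TP replicate 2 may contribute: 95.8% of 24 adipose genes outside the fixed list exceeded all other libraries there by more than the median gene did, among them Sncg at 871 TPM and Scd at 375 TPM. Whether it accounts for the macrophage and matrix genes too, and whether the 2 rats differed in injury, stays open.

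The stress protein list had its highest medians in the TP+hucMSC-Exs libraries. Composition of TPM is argued against. The list's median difference from the mean of the other 4 libraries, 2 of them controls, was 3.94 log2 units as deposited and 3.40 after median-of-ratios scaling. Without the listed digestive enzymes it was 3.75, but that rescaling kept LOC103689940 and LOC103690354. Of 13 members, those highest in both TP+hucMSC-Exs libraries numbered 9 as deposited, 9 without the listed enzymes and 6 after median-of-ratios scaling. Whether TP replicate 2 alone gave the difference from the TP group was tested by leaving it out. The list then still passed camera with its preset correlation under both scalings (larger camera adjusted p = 0.0371). That p-value cannot decide the question, since the TP group was then 1 library with no spread of its own. Relative to the median gene, the list stood at 1.44 in TP replicate 1, below 3.60 and 4.04 in the treated libraries. The order therefore held for TP replicate 1 too, which is 1 rat. A STAT3 and acute-phase programme may be involved. After median-of-ratios scaling only 31.2% of 16 measured targets were highest in both libraries, against 11.9% of all genes, which leaves it undecided. Of the targets counted, Stat3, Junb, Bcl3 and Cebpd had their highest TPM as deposited in TP replicate 2. Lbp stood there at 5.29 TPM, between the treated values of 4.03 and 10.17 TPM. Itih4, not counted, was highest in both treated libraries as deposited, at 4.21 and 5.29 TPM. After the same scaling 0 of 3 gastric mucosa genes were highest in both, a share under the bound of 20% set beforehand. It was left undecided because 3 measured genes are too few, by the requirement added afterwards. Exosome treatment, a later or stronger injury response in these 2 rats, and a difference in the tissue sampled stay open, as each is tied to the same 2 animals.

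The opposite movement of the injury and exosome comparisons may come from the shared TP libraries. Once no TP library was shared, the covariance across genes was 0.068 and 0.320 and no longer below 0. TP replicate 1 itself lay near the controls, with a correlation of 0.954 to control replicate 1. The split therefore rests largely on TP replicate 2 and cannot decide whether sharing alone gave the negative sign. The design has too few TP libraries to separate a reversal from the effect of sharing them.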
